A study of Mus musculus with 12 samples.

How the data were processed

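RNA from liver and lung of female B6C3F1/Nctr mice, labelled with a single dye (Cy3), was measured on 12 Agilent 1-colour expression arrays. The groups were taken from the titles and source names: untreated liver, liver with acrylamide at 0.7 mM, untreated lung and lung with acrylamide at 0.7 mM, with 3 arrays each. Each array is named here by its tissue, treatment and the number in its title. The tissue entry and the design text of all 12 arrays say liver, whereas the titles and source names of 6 arrays say lung, so marker genes were checked before any comparison. The route and length of exposure are not given in the sources used here.

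The deposited array files hold 1 linear Cy3 intensity for each of 62976 spots, with accession, gene name and Entrez number. The scanner values were made with Agilent Feature Extraction 10.7, per the submitters' processing notes. Whether the deposited intensity had its background subtracted is not stated. All values are above 0, and background flags and probe identifiers were not used here, so spots of the same probe could not be averaged. The authors' series matrix holds the same intensities multiplied by 1 factor per array, which sets the 75th percentile to 1000, and it was used as an alternative.

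The 1319 control spots, recognised by their accessions, were left out, and log2 intensity was centred on each array's 75th percentile over the remaining 61657 spots. Gene symbols came through the Entrez number for 38054 spots and through the accession for 688 spots, using a RefSeq table of assembly GRCm38.p6 for names only. Another 2269 spots kept the name in the file, and 20646 spots had no name and entered only the alternative that tests each spot. A spot counted as above background where it exceeded the 95th percentile of the 308 negative control spots of its array. Spots above background on at least 3 arrays of the fit were tested, and each gene symbol was represented by its spot with the highest mean. No file gave a scan date. The slide in the titles follows the tissue, so slide and tissue cannot be told apart, and the slide row in the titles was used as a block. In liver, row 1 held acrylamide 27 and 30 and controls 1 and 3, and row 2 acrylamide 29 and control 4. In lung, row 1 held acrylamide 28 and 30 and control 5, and row 2 acrylamide 29 and controls 4 and 6. Row and treatment are therefore partly confounded in lung, and each lung row leaves a single array in 1 of the groups.

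Arrays were fitted within each tissue with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the acrylamide minus control contrast. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and genes at unadjusted p under 0.05 with a fold of at least 1.5 were counted beside it. The difference between the tissues was the interaction contrast over all 12 arrays. For a gene above background on no array of 1 group, the fold is given as a lower bound. As nothing in the labels says that the arrays of a group came from separate animals, p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

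The 48 gene lists held 1021 entries on the array, some genes being in several lists, and covered pathways and cell types. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and fry's mixed test asked whether members changed in either direction. The mixed test and the list test of the interaction were added later. Groups, the other tests, lists, the naming rule and the alternatives other than those added later were fixed before the data were examined. The rule names the 12 genes with the largest rise and the 12 with the largest fall in each tissue whose arrays did not overlap, filled from unadjusted results where none passed. It also takes a fixed set of genes of acrylamide metabolism, DNA damage and chromatin, 2 to 4 members with the largest difference of each list described, passing over clone names and predicted genes, and 6 genes in each direction for the interaction. Other names were chosen after their values were seen, and a few genes that the rule takes are not reported here.

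The fits were tested on simulated data made from the spread of each comparison. With 50 genes changed at each size, the liver fit called 0% at 1.5-fold, 24.0% at 2-fold, 66.0% at 4-fold and 72.0% at 8-fold among 21171 genes. The lung fit called 10.0%, 50.0%, 70.0% and 90.0% at those sizes among 22257 genes, and each simulation also called 7 unchanged genes. Simulated genes were independent, and all arrays shared 1 spread per gene, so correlated genes and arrays of unequal quality were not represented. The shares may therefore not hold for the real arrays.

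The alternatives were quantile and median scaling, the series matrix, no background filter and a filter on every array, the mean of a gene's spots, every spot, an intensity trend, arrayWeights, the slide row as a block, 1 fit of all 12 arrays, the title number as a random block, an estimated correlation and leaving out each array. A filter at 16 times background, the removal of genes of the other tissue and fits within a slide row were added after seeing the data. A single gene that missed the threshold was counted as turned only where its sign changed with an unadjusted p under 0.05 in either setting. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.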

Results

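The series asked what acrylamide did to gene expression in mouse liver and lung, under a title on epigenetic effects. Acrylamide is a small reactive amide that Cyp2e1 converts to the epoxide glycidamide. The 75th percentile of intensity was 294.5 to 621.5 on liver arrays and 839.4 to 1376 on lung arrays. Liver acrylamide 30 had the lowest percentile, 34287 spots above background and a background limit of 16.77, against 2.35 to 4.45 on the other arrays.

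Surfactant and secretory genes of alveolar type 2 cells were high on the 6 arrays whose titles say lung, and hepatocyte genes were high on the 6 whose titles say liver. The mean of the alveolar type 2 list minus that of the hepatocyte list was 6.28 ± 0.48 log2 units (SD, n = 6) in lung and -10.06 ± 0.77 (SD, n = 6) in liver. The groups lay 16.33 log2 units apart without overlap (two-sided exact permutation test over 924 splits, p = 0.00217), and the arrays are called lung and liver accordingly.

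In liver, Dbp, a transcription factor driven by the circadian clock, was 2.34 ± 0.26 log2 units higher (SE, n = 3 per group, adjusted p = 0.491), and Per3, a period gene, was 1.44 ± 0.24 higher (adjusted p = 0.665). Nfil3, a repressor of Dbp targets, was -1.07 ± 0.18 log2 units apart (adjusted p = 0.665). The clock list did not pass, with 11 of 21 members higher and 10 lower (camera adjusted p = 0.422). Egr1, an immediate early gene, differed by -3.35 ± 0.97 log2 units, and Ppard, a nuclear receptor of lipid metabolism, by -1.66 ± 0.22, with adjusted p = 0.784 and 0.59. Sult2a4 and Sult2a1, sulfotransferases, differed by -2.27 and -1.90, and the neutrophil protein gene S100a9 by -1.81. The biliary factor Sox9 differed by -2.05 and the B cell gene Fcer2a by -2.21.

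None of these passed: limma called 0 of 21171 genes in liver, while 1280 genes had an unadjusted p under 0.05, against 1059 by chance. Of these, 786 reached 1.5-fold, 358 higher and 428 lower, and groups did not overlap for 12.2% of all genes, where chance gives 10%. Quantile scaling made 33.1% of the 1.5-fold differences higher, against 45.5%. Without liver acrylamide 30 there were 1897 such genes, and without acrylamide 27 Lingo2 was called, at 4.53 ± 0.21 log2 units (SE).

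The largest liver rise was that of Sftpc, the surfactant protein C gene of alveolar type 2 cells, at 5.26 ± 1.97 log2 units (SE, adjusted p = 0.784). It came from acrylamide 27 and 29, which lay 9.09 and 5.82 log2 units above the control mean, while on acrylamide 30, as on control 1, its spot was not above background. The club cell genes Scgb1a1 and Cbr2 lay 5.61 and 4.84 above it on acrylamide 27 and 4.55 and 3.77 on acrylamide 29. Of the 12 largest rises, 10 lay within 4-fold of background, among them Unc13c, Sv2c, Tceal7, Olfr996, Siglecf, Klra23, Tctex1d4, Krtap7-1 and the developmental gene T. Mesp1 was not above background on any control array and was at least 2.71 log2 units higher.

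**Figure D1:**
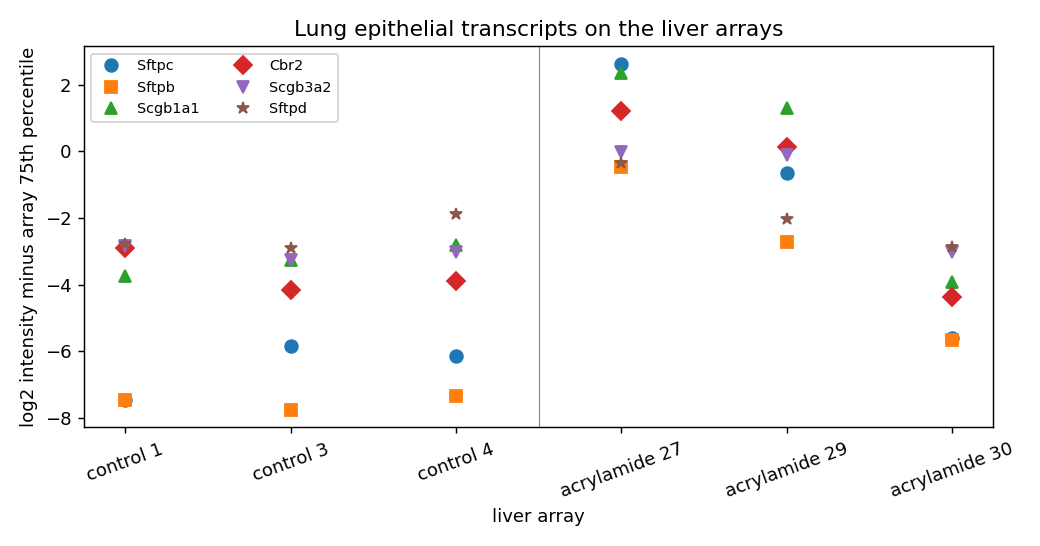
Log2 intensity minus the array's 75th percentile of 6 lung epithelial genes on each liver array, 1 point per gene and array, with controls left of the line. Sftpc stands at 2.63 on acrylamide 27 and -0.65 on acrylamide 29, against -5.83 or lower on the controls, and its points on acrylamide 30 and control 1 were not above background.

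Macrophage genes moved together in liver. Of 15 tested Kupffer cell and macrophage genes 14 were higher, with a median of 0.43 log2 units, led by Lyz2, a lysozyme (1.13 ± 0.49, SE), and Vsig4, a complement receptor (0.80 ± 0.33), and the list rose (camera adjusted p = 7.92e-07, adjusted p = 0.515 with an estimated correlation). Xenobiotic cytochrome P450s rose by a median of 0.22, 23 of 29 being higher, with Cyp2d22 at 0.55 and Cyp2a4 at 0.54, while the members with the largest differences were Cyp1b1, near background (0.88 ± 0.86, SE), and Cyp2s1 (-0.69 ± 0.66) (adjusted p = 0.000908, adjusted p = 0.515 with an estimated correlation). Both lists kept their calls in all 20 other settings that left the preset correlation in place, but the macrophage median was 0.25 without control 3 and the P450 median 0.13 without control 1. The alveolar macrophage list also rose, 12 of 14 genes being higher (adjusted p = 0.0139, adjusted p = 0.515 with an estimated correlation). Its leading gene Siglecf was near background, and the scavenger receptor Marco stood at 0.60. Without acrylamide 27 this list had a median of 0.10 (adjusted p = 0.0834), against 0.25 with all arrays, and without genes of the other tissue 0.21 (adjusted p = 0.0894), with fewer genes.

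Extracellular matrix genes fell, 27 of 35 being lower, with Col1a1 at -1.37 and the collagen cross-linker Lox at -1.28 (adjusted p = 0.00101, adjusted p = 0.515 with an estimated correlation). The B and plasma cell list fell by a median of -0.90, 10 of 11 genes being lower, with Fcer2a, the antibody joining chain Jchain (-1.20) and Cd79b (-1.08) in front (adjusted p = 0.00337, adjusted p = 0.515 with an estimated correlation). Its median over the control mean was -0.33, -1.04 and -1.21 on acrylamide 27, 29 and 30, and 0.33, -0.69 and 0.37 on controls 1, 3 and 4. The median difference was -0.58 without control 1 and -1.38 without control 3. The T and NK cell list fell too, 15 of 18 genes being lower, with the receptor Il7r at -0.94 and the adhesion molecule Cd2 at -0.60 (adjusted p = 0.0138, adjusted p = 0.515 with an estimated correlation). That call was lost with the mean of spots and every spot (camera adjusted p = 0.051 and 0.12), at medians of -0.19 and -0.17. Mesothelium, with Wt1 at -2.17 and Krt19 at -1.21, and lung mesenchyme, with Cnn1 at -1.61 and Col1a1 shared with the matrix list, fell at adjusted p = 0.0475 each (adjusted p = 0.56 and 0.515 with an estimated correlation). The mesothelium median over the control mean was -1.13, 0.13 and -1.30 on acrylamide 27, 29 and 30, and -0.20, 0.04 and 0.22 on controls 1, 3 and 4. Mesothelium kept its call in 10 of 19 other settings with the preset correlation, and lung mesenchyme in 12 of 20.

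Periportal hepatocyte genes rose by a median of 0.23, 11 of 14 being higher, with the gluconeogenic enzyme Pck1 at 0.64 and Hsd17b13 at 0.58 (adjusted p = 0.00614, adjusted p = 0.515 with an estimated correlation). Pericentral hepatocyte genes were also higher, 10 of 14, by a median of 0.18 (camera adjusted p = 0.071), so a shift particular to the periportal zone was not shown. In the general hepatocyte list 15 of 23 genes were lower (camera adjusted p = 0.993). Acrylamide metabolism genes rose by a median of 0.14, 18 of 23 being higher, with the glutathione transferases Gstm4 at 0.63 and Gsta2 at 0.61 (adjusted p = 0.0144, adjusted p = 0.56 with an estimated correlation). Their median over the control mean was -0.12, 0.105 and 0.35 on acrylamide 27, 29 and 30, and -0.06, 0.02 and 0.06 on controls 1, 3 and 4. Acrylamide 27 therefore lay below every control. Without acrylamide 27 the median difference was 0.26. Erythroid genes rose with Ahsp, near background, at 0.79 and Hbb-b1 at 0.69 (adjusted p = 0.00819, adjusted p = 0.515 with an estimated correlation). Proliferation genes rose, 24 of 35 being higher, with Cdk1 at 1.59 and Kif11 at 0.83 (adjusted p = 0.00948, adjusted p = 0.56 with an estimated correlation). Their median over the control mean was 0.36, 0.16 and 0.16 on acrylamide 27, 29 and 30, and 0.25, -0.22 and -0.03 on controls 1, 3 and 4, so the groups overlapped. Male-biased liver genes rose, 13 of 20 being higher, with Cyp4a12a at 0.95, although the largest difference, that of the repressor Bcl6, was -1.32 (adjusted p = 0.023, adjusted p = 0.515 with an estimated correlation). Cholesterol synthesis genes fell, 22 of 24 being lower, with Lss at -0.74 and Mvd at -0.52 (adjusted p = 0.0138, adjusted p = 0.698 with an estimated correlation). Their median over the control mean was 0.13, -0.31 and -0.48 on acrylamide 27, 29 and 30, and 0.08, 0.17 and -0.20 on controls 1, 3 and 4. The call was lost with quantile scaling, the mean of spots and every spot (camera adjusted p = 0.0675, 0.0833 and 0.101), at medians of -0.16, -0.14 and -0.19.

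Epigenetic enzymes fell by a median of -0.10 in liver, 44 of 56 being lower (adjusted p = 0.0355, adjusted p = 0.56 with an estimated correlation). The median was -0.17 without control 1 or acrylamide 30 and -0.06 without acrylamide 29. The call was lost with quantile scaling, the mean of spots and every spot (camera adjusted p = 0.0772, 0.175 and 0.202), at medians of -0.08, -0.06 and -0.07. It was kept in 11 of the 20 other settings with the preset correlation. Adjusted over the list alone, 2 members passed, against 0 over all genes: Dnmt3b, a DNA methyltransferase, fell by 0.98 ± 0.17 log2 units (SE), and Hdac2, a histone deacetylase, rose by 0.97 ± 0.17. Kdm6b, a histone demethylase, and Tet2 differed by -0.73 each and Tet1 by 0.48, while Dnmt1, Dnmt3a, Tet3, Hdac1 and Ezh2 differed by -0.11, -0.03, -0.01, -0.05 and -0.10. Adjusted over the list alone, Dbp, Per3 and Nfil3 of the clock list passed, as did the p53 targets Bbc3 (-1.22) and Plk2 (-0.82), Pdk4 (-1.47) of the fatty acid oxidation and gluconeogenesis lists, and Slc2a2 (0.67) of the latter, against 0 over all genes. Cyp2e1 and Ephx1, an epoxide hydrolase, differed by -0.13 and 0.20, the p53 targets Cdkn1a, Mdm2, Ccng1 and Phlda3 by -1.04, 0.08, 0.38 and 0.14, and the oxidative stress genes Nqo1 and Hmox1 by 0.24 and 0.09, with adjusted p of 0.784 or above.

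Of the 48 lists, 15 passed in liver at the preset correlation, 8 up and 7 down, and 0 with an estimated correlation. Without liver acrylamide 30, 12 of the 15 lost their call, with adjusted p from 0.0634 for extracellular matrix to 0.564 for cholesterol synthesis and acrylamide metabolism, leaving the Kupffer cell, P450 and alveolar macrophage lists. The medians of extracellular matrix (-0.32), periportal (0.29), proliferation (0.26), T and NK cell (-0.22) and epigenetic (-0.17) genes were then no smaller than with all arrays, while those of the other 7 lists shrank, to -0.74 for B and plasma cell, 0.33 for erythroid, -0.47 for mesothelium, -0.14 for lung mesenchyme, -0.09 for cholesterol synthesis, 0.09 for acrylamide metabolism and 0.08 for male-biased genes. Single other arrays also ended calls, some with a median about as large. The epigenetic list had medians of -0.12, -0.06, -0.09 and -0.09 (adjusted p = 0.0763, 0.128, 0.0784 and 0.143) without acrylamide 27, acrylamide 29, control 3 and control 4, against -0.10 with all arrays. Mesothelium had -0.62, -0.73 and -0.50 (0.277, 0.0641 and 0.136) without acrylamide 27, control 3 and control 4, against -0.71. Lung mesenchyme had -0.20, -0.21 and -0.17 (0.216, 0.165 and 0.0561) without control 1, acrylamide 27 and control 3, against -0.19. Cholesterol synthesis had -0.21, -0.19 and -0.11 (0.105, 0.122 and 0.149) without control 1, acrylamide 29 and control 3, against -0.22. Erythroid had 0.33 and 0.31 (0.0834 and 0.0572) without acrylamide 27 and control 3, against 0.44, and proliferation 0.09 and 0.16 (0.188 and 0.0567) without controls 3 and 4, against 0.21. T and NK cell had -0.17 each (0.0698 and 0.113) without acrylamide 29 and control 4, against -0.22, acrylamide metabolism 0.10 (0.0536) without control 1, against 0.14, and male-biased 0.13 (0.118) without control 3, against 0.18. With arrayWeights 10 lists passed. Extracellular matrix and acrylamide metabolism were not among them, at medians of -0.24 and 0.11 (camera adjusted p = 0.0854 and 0.227). Nor were erythroid and lung mesenchyme, at 0.22 and -0.14 (0.223 each), or mesothelium, at -0.39 (0.388). Cholesterol synthesis and male-biased genes did not pass either, at -0.10 and 0.08 (0.445 and 0.548). With the slide row as a block all 15 lists passed, beside 818 genes at 1.5-fold. Within slide row 1 there were 627 such genes, and the B and plasma cell, epigenetic and T and NK cell lists lost their call (adjusted p = 0.0631, 0.352 and 0.32), with medians of -0.57, -0.05 and -0.09. The other 33 lists had adjusted p of 0.071 to 0.993, and in 7 of them, among them p53 targets and gluconeogenesis, the median, mean and test differed in sign.

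In lung, Dbp was again high, at 1.56 ± 0.43 log2 units (SE, n = 3 per group, adjusted p = 0.96), and Nr1d1, which codes for the clock repressor REV-ERB alpha, was 1.21 ± 0.22 higher (adjusted p = 0.956). Egr1 differed by -1.33 ± 0.15 log2 units (adjusted p = 0.652). Sele, the endothelial adhesion molecule E-selectin, was 1.32 ± 0.23 higher, and Mup6, of the major urinary protein family, 1.28 ± 0.31 higher. The fetal-type globin gene Hbb-bh2 had the largest rise, at 2.65 ± 0.98.

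No gene passed: limma called 0 of 22257 genes in lung, and 1101 had an unadjusted p under 0.05, against 1113 by chance. Of these, 356 reached 1.5-fold, 145 higher and 211 lower, and 200 lay within 4-fold of background. The share that was higher, 40.7%, became 52.6% with the slide row as a block and 32.2% with median scaling. Groups did not overlap for 10.9% of all genes, where chance gives 10%. Among the largest falls, 9 of 12 lay near background, including Vmn1r174 (-1.73), Gapdhs (-1.53), Olfr470 (-1.47), B3gat2 (-1.34) and Stk32c (-1.25). Hoxd3 was not above background on any control array and was at least 1.11 log2 units higher.

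Interferon response genes fell in lung by a median of -0.18 log2 units, 31 of 34 being lower, with Tap1 at -0.31, Oas2 at -0.31 and Mx1, an antiviral GTPase, at -0.31 (camera adjusted p = 0.00012, adjusted p = 0.889 with an estimated correlation). That list kept its call in all 21 other settings with the preset correlation, but its median was -0.10 without control 6. It was -0.12 within slide row 1 and -0.19 within slide row 2. The Kupffer cell and macrophage list rose by a median of 0.30, 13 of 15 genes being higher, with the complement gene C1qa at 0.49 and the scavenger receptor Cd163 at 0.47 (adjusted p = 0.00332, adjusted p = 0.889 with an estimated correlation). Its median was 0.13 without control 4 and 0.19 without acrylamide 30. Alveolar macrophage genes rose, 13 of 15 being higher, with Ear1 at 0.49 and Marco at 0.42 (adjusted p = 0.0294, adjusted p = 0.889 with an estimated correlation). Their median was 0.03 within slide row 1 and 0.34 within slide row 2, and with the row as a block it was 0.10 (adjusted p = 0.112).

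All 14 alveolar type 2 genes were lower, by a median of -0.09 with Nkx2-1, a lung lineage factor, at -0.33 and Lpcat1, a surfactant lipid enzyme, at -0.27, and the list fell (adjusted p = 0.0294, adjusted p = 0.889 with an estimated correlation). That median was -0.16 without acrylamide 28 and -0.18 without control 4. The list kept its call in 11 of the 21 other settings with the preset correlation. Gluconeogenesis and glucocorticoid targets rose, 18 of 22 being higher, with Pck1 at 0.98 and Zbtb16 at 0.92 (adjusted p = 0.00715, adjusted p = 0.889 with an estimated correlation). Heat shock and metallothionein genes rose with Hspa1b at 0.87 and Hspa1a at 0.82 (adjusted p = 0.0294, adjusted p = 0.889 with an estimated correlation). Without control 6 their median was -0.0018, and with the slide row as a block it was 0.12 (adjusted p = 0.0957), against 0.15. Hepatocyte genes rose by a median of 0.32, 21 of 23 being higher, with Hpd at 0.77 and Ahsg at 0.61 (adjusted p = 0.00793, adjusted p = 0.889 with an estimated correlation). Their median over the control mean was 0.67, 0.64 and -0.24 on acrylamide 28, 29 and 30, and -0.10, -0.39 and 0.62 on controls 4, 5 and 6. The median difference was 0.69 and 0.66 without acrylamide 30 and control 6. With the slide row as a block the hepatocyte median was 0.49 (camera adjusted p = 7.36e-07 at the preset correlation), and within slide rows 1 and 2 it was 0.67 and 0.40. That p takes the genes as nearly uncorrelated, at 0.01, whereas the correlation estimated for this list without the block was 0.776. No test with an estimated correlation was run with the block.

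Adjusted over the list alone, 8 members of the clock list passed in lung, against 0 over all genes, while the list itself did not (camera adjusted p = 0.48). Nr1d1, Nr1d2 (0.99) and Dbp rose, and Arntl, which codes for BMAL1 (-0.92), its relative Npas2 (-0.84), Cry1 (-0.86), Nfil3 (-0.41) and Leo1 (-0.39), a transcription elongation factor of that list, fell. Likewise the male-biased genes Mup1 (1.18), Mup20 (1.14) and Mup21 (1.09) rose and Cspg5 (-0.35) fell, and Sele rose and the immediate early genes Egr1 and Fos (-0.77) fell in the acute phase list. Over all genes, Tet1 differed by -0.70, against 0.48 in liver, and Gdf15, a stress cytokine, by 0.65, against -0.81 in liver (adjusted p = 0.96 and 0.956 in lung). Dnmt3b, Cyp2e1, Cdkn1a and Nqo1 differed by -0.07, 0.28, 0.37 and 0.24.

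Of the 48 lists, 7 passed in lung, 5 up and 2 down, and 0 with an estimated correlation. Leaving out single arrays ended every call except that of the interferon list, some with a median about as large. The hepatocyte list had medians of 0.14, 0.24 and 0.13 (adjusted p = 0.224, 0.13 and 0.502) without acrylamide 28, acrylamide 29 and control 5, against 0.32 with all arrays. Gluconeogenesis had 0.11, 0.12 and 0.16 (0.133, 0.173 and 0.106) without acrylamide 28, control 5 and control 6, against 0.24. Alveolar type 2 had -0.11, -0.09, -0.08 and -0.07 (0.0735, 0.116, 0.155 and 0.183) without acrylamide 29, acrylamide 30, control 5 and control 6, against -0.09. Alveolar macrophage had 0.12, 0.02 and 0.22 (0.146, 0.307 and 0.0611) without acrylamide 30, control 4 and control 6, against 0.155. Heat shock had 0.10 and -0.0018 (0.283 and 0.81) without acrylamide 30 and control 6, against 0.15, and the Kupffer cell list 0.19 (0.0627) without acrylamide 30, against 0.30. With the slide row as a block 12 lists passed, beside 449 genes at 1.5-fold. Without control 5, 565 genes reached 1.5-fold. Slide row 1 had control 5 as its only control, and row 2 had acrylamide 29 as its only treated array. Medians alone are therefore given within rows. Within row 1 the alveolar macrophage and Kupffer cell lists had medians of 0.03 and 0.11, and within row 2 gluconeogenesis had 0.17. Alveolar type 2 had -0.18 and -0.11 within rows 1 and 2, and heat shock 0.05 and 0.19. The other 41 lists had adjusted p of 0.0653 to 0.97, and in 8 of them the median, mean and test differed in sign.

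**Figure D2:**
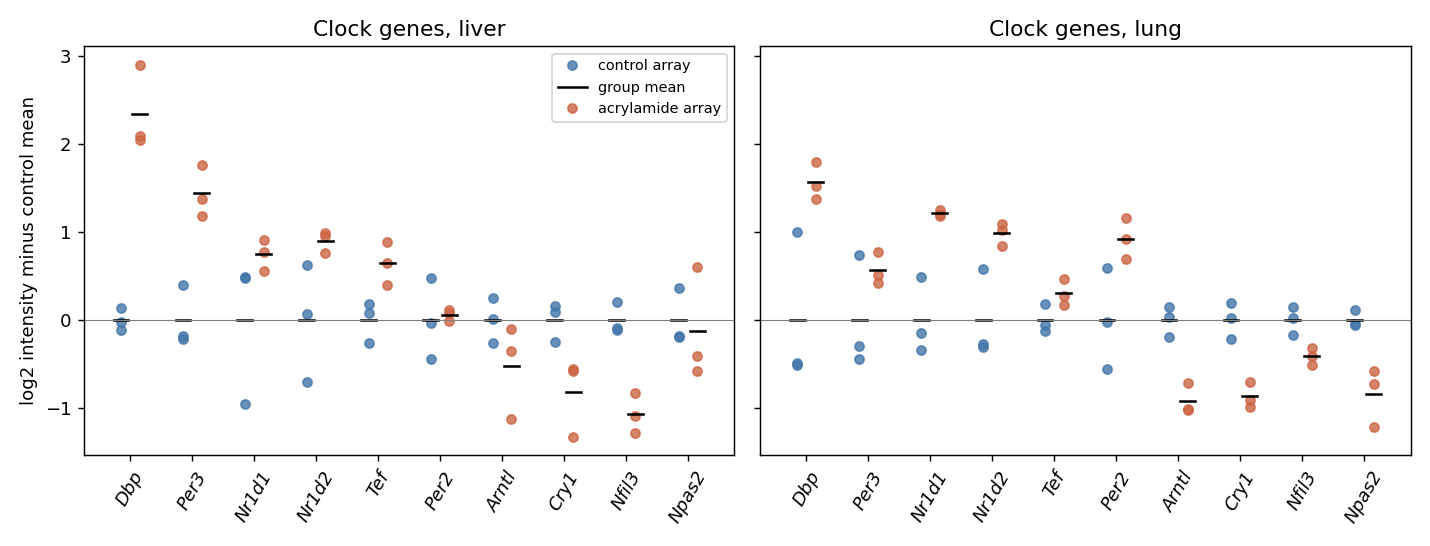
Log2 intensity of 10 clock genes minus the control mean, for each array of liver (left) and lung (right), 1 point per array, with black lines at group means. The mean of Dbp stands at 2.34 in liver and 1.56 in lung, and that of Cry1 at -0.82 and -0.86.

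Across tissues, few genes moved together. Dbp, Nr1d2, Olfr215, Coro6, Serpina3g, Oc90 and 1 predicted gene were higher in both tissues at unadjusted p under 0.05 and 1.5-fold, 7 genes where independent lists give 1.63. Egr1, Cry1, Ccr6, a chemokine receptor, Ypel2 and 1 unnamed clone were lower in both, 5 genes where independent lists give 2.87. These were named after their values were seen, and 4 genes moved each opposite way, where independent lists give 2.16 and 2.17. Across 20416 genes, which are not independent replicates, the log2 differences correlated with Pearson's r = 0.0904 and Spearman's rho = 0.138. Without lung control 4, r was 0.028, and without lung acrylamide 30 it was 0.0423.

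Ppard, at -1.66 in liver and -0.06 in lung, had the lowest unadjusted p of the interaction apart from 1 predicted gene, with a lung effect minus liver effect of 1.60 ± 0.23 log2 units (SE). That of Loxl1, a lysyl oxidase family gene, was 1.37 ± 0.26, with -1.27 in liver and 0.10 in lung. In the other direction, Ccdc158 (1.45 in liver and -0.44 in lung) had -1.89 ± 0.31 and Hdac2 (0.97 and -0.23) had -1.19 ± 0.22. None passed: limma called 0 of 23012 genes (lowest adjusted p = 0.547), and 1025 had an unadjusted p under 0.05, against 1151 by chance. Without liver acrylamide 30, 139 genes passed, among them Sftpc, Sftpb, Scgb1a1 and Cbr2, and arrayWeights called 136, of which 81 were shared. The extracellular matrix, alveolar type 2, interferon response and hepatocyte lists were among 8 lists that differed between tissues at the preset correlation, and 0 did with an estimated one (lowest adjusted p = 0.246).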

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

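The interaction test was planned for genes and extended to the lists later, and the tests of lung transcripts in liver, hepatocyte transcripts in lung and clock genes were chosen only after the result was seen. The treatment effect on 8 lists differed between lung and liver in the interaction test at the preset correlation. Adjusted p was 0.000523 for extracellular matrix, 0.00207 for interferon response, 0.00581 each for alveolar type 2 and lung mesenchyme, 0.0215 for lung endothelium, 0.0321 each for hepatic stellate and hepatocyte, and 0.0439 for T and NK cells. None held with an estimated correlation, where the lowest adjusted p was 0.246. Extracellular matrix had a median of -0.30 log2 units in liver and 0.03 in lung, and alveolar type 2 0.42 and -0.09, but in the liver fit, which did not test Sftpb and read Nkx2-1 from another spot (-0.46, against 0.50), that list had 0.17 (not called, adjusted p = 0.215), with 0.36, 0.49 and -0.06 on acrylamide 27, 29 and 30.

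Lung epithelial transcripts stood on liver acrylamide 27 and 29. A fault of single spots was argued against, since 9 and 6 of 59 lung genes lay over 2 log2 units above the highest control. The first test asked whether lung RNA at the share that Sftpc gives, 1.60% and 0.162%, predicts the other lung genes, and they lay -2.55 and -0.92 log2 units from that level, which argues against that share, although Sftpc lay at the top of the intensity range in lung, so that this share may be too high. A second test, against the gap between tissues, gave rho = 0.751 and 0.454 but also 0.476 on acrylamide 30, where 0 lung genes passed that limit although some, such as Stmn2, lay below it by little, and it was replaced by the correlation with the lung level, 0.415 and 0.392, which decides neither way. Lung RNA at a smaller share, lung epithelial RNA and acrylamide treatment may each contribute and stay open, since the 0.23 by which Sftpc on acrylamide 30 lay above the highest control came from a spot not above background and decides nothing.

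Hepatocyte transcripts varied together across lung arrays, with a median correlation of 0.827 between genes. Liver RNA would hold them in 1 ratio to their liver level. Over the 8 genes below a brightness limit in liver, the SD of that log2 ratio was 0.965, between bounds of 0.5 and 2. The median of that log2 ratio was -10.7. Alb, above that limit, stood at -4.86, which goes against 1 ratio for that gene. Its scaled log2 level on liver controls 1, 3 and 4 was 8.35, 8.52 and 8.61, below Cyp2e1 at 8.72, 8.61 and 8.98. Alb was therefore not at the ceiling of those arrays, although whether its signal flattened at a lower level was not measured. A first bound of 1 was dropped because it had been set after the value could be foreseen. The highest control lay 0.864 log2 units above the lowest acrylamide array, on 1 array each. Liver RNA and treatment therefore may both contribute and cannot be told apart with 3 arrays per group.

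Clock genes moved in parallel in both tissues, with r = 0.786 across 21 genes of the clock list, 17 in the same direction. Liver acrylamide 30 alone was argued against, as r was 0.75 without it. Only 2 of 200 relabelings, the observed one included, gave as large an r, the highest other being 0.827. The list was picked out after all 48 had been seen, however, and over the 48 lists the adjusted p of this exact test was 0.24. It was the same for the acute phase list with 1 of 200, the observed labelling alone. A difference in time of tissue collection may give the same r = 0.786, no label gives a time, and treatment and time cannot be told apart.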

How the results depend on the processing

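Tests within a slide row and at 16 times background were added after the data were seen, and their causes, like those of the other changes, were not tested unless fewer arrays or genes were fitted. Adjusted calls stayed at 0 in lung in every setting, and in liver rose to 2 with all 12 arrays in 1 fit (Angptl2 and Ppard) and to 1 without acrylamide 27, the range without 1 array being 0 to 1. Liver genes at 1.5-fold numbered 453 with the filter on every array, 2229 with every spot, 2082 with arrayWeights, 415 at 16 times background and 697 to 1897 without 1 array, the highest without acrylamide 30. Liver lists numbered 0 with an estimated correlation and 4 to 14 without 1 array, with 4 without acrylamide 30 and 8 without control 3. Lung genes at 1.5-fold numbered 987 with every spot, 228 with all 12 arrays, 91 at 16 times background, 1001 and 603 within slide rows 1 and 2, and 381 to 565 without 1 array. Lung lists numbered 12 with median scaling, 14 with every spot, 12 with the row block, 0 with an estimated correlation, and 6 to 16 without 1 array, with 16 without control 4 and 11 without control 6. Interaction calls numbered 136 with arrayWeights and 0 to 139 without 1 array, with 7 without liver acrylamide 27. The correlation between tissues was 0.159 with the filter on every array and 0.028 to 0.115 without 1 array.

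Values that turned sign were Cd8a in liver (0.0907) with the mean of spots, Nlrp4f in lung with all 12 arrays (0.18, from another spot), Reg3g in lung without control 6 (-2.84, against 2.42 without control 4), and the heat shock list without control 6 (-0.0018, against 0.253 without control 4). Within slide row 1 in lung, Retn was -1.59, Reg3g -3.00, Bpifb1 -2.42, Dgat2 -0.46, Mcpt4 -0.89, Krt5 -1.35, and Itga2b -0.97. The alveolar macrophage median there stayed positive, at 0.026 against 0.155 with all arrays, and only the direction of its camera test turned. Control 5 was the only control in that row, so these values rest on that array. Within slide row 2 liver had 1 array per group and was not run, nor was normexp, whose columns were not used here. Of the genes at 1.5-fold, 39.8% in liver and 56.2% in lung lay within 4-fold of background, against 18.4% and 12.2% of all genes tested.

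The title numbers 4, 29 and 30 occur in both tissues, and pairs had correlations of 0.0127, -0.0215 and -0.144 of their deviations, against -0.0649 to 0.116 for other pairs, so the data gave no ground for pairing them, which does not show whether they came from the same animals. With the number as a random replicate block the interaction called 0 genes (lowest adjusted p = 0.79, consensus correlation -0.181), beside 898 at unadjusted p under 0.05.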

Other observations

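The tests of how often splits of the arrays gave as large a count were planned, whereas fry's mixed test was not among the tests fixed beforehand and was chosen later. Members of 4 lists changed in either direction in liver by fry's mixed test: circadian clock (adjusted p = 0.00594), ciliated cell (0.0203), p53 targets (0.0259) and extracellular matrix (0.032). Among the p53 targets 15 of 28 were higher and 13 lower, with Bbc3 at -1.22 and Cdkn1a at -1.04. In lung the acute phase list did (adjusted p = 0.0051), with the chemokines Cxcl5 at -1.46 and Ccl2 at 0.78 beside Egr1 at -1.33 and Sele at 1.32. The ciliated cell list is one of the lung cell types, and its leading member in liver, Dynlrb2, was among the 59 lung genes above. On acrylamide 27, 29 and 30 Dynlrb2 lay 2.41, 1.11 and 1.12 log2 units above the liver control mean, and the list median was 0.11, 0.06 and 0.46. The Dynlrb2 spot on acrylamide 30, the array with the highest background limit, was not above background, so its 1.12 shows no rise. How far that limit raised the list median on acrylamide 30 was not measured. Whether lung transcripts on liver arrays gave the mixed test result of the ciliated cell list was not tested.

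The observed split is counted among the 10 splits of each tissue and among those giving as many. In liver, 786 genes at 1.5-fold compared with 1338 for the highest other split, 3 of 10 splits giving as many. The 15 liver lists compared with 11, and the 1 of 10 giving as many was the observed split itself. In lung, 356 genes compared with 607, 8 of 10 giving as many, and 7 lists with 23, 10 of 10. Adjusted calls were 0 in all 10 splits of each tissue by limma, beside 1280 and 1101 genes at unadjusted p under 0.05. With 3 arrays against 3, the splits are too few for a share under 0.05. For the interaction, the observed count was 0, so all 100 drawn relabelings gave as many by construction, which decides nothing, and the highest other was 3.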
